A study of Homo sapiens
Mus musculus with 5 samples.

How the data were processed

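RNA sequencing libraries of 5 tumors were compared, 3 brain tumors and 2 orthotopic lung tumors grown from the human lung adenocarcinoma line H2030-BrM3 in athymic nu/nu mice. The deposited values are RPKM, reads scaled to gene length and to library size, in 1 table of 25524 human genes and 1 table of 24628 mouse genes. Per the labels the builds were hg38 (GRCh38) and mm10 (GRCm38). The aligner, the counting tool, the gene lengths used for RPKM and the rule that assigned reads to a species are not given in the sources used here. The human table was read as expression of the cancer cells and the mouse table as that of the host. Columns were joined to samples by the library numbers in the sample descriptions, and 0 per-sample columns were left unmapped. Symbols that stand for more than 1 gene (148 human, 36 mouse) were kept apart by Ensembl identifier.

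Whole reads were recovered from the deposited RPKM, since the values of a gene in different libraries stand in whole-number ratios after 1 factor per library. All 25524 human and 24628 mouse genes gave whole numbers, within 1.2e-10 and 7.3e-11 reads, and after a random factor on 1 library 10.9% and 5.71% of genes did. Recovered reads are known up to a common divisor, so that totals are lower bounds, and for 4393 human and 3995 mouse genes above 0 in 1 library the number of reads is not fixed. The ratio of the RPKM denominators to the recovered totals of the same species, relative to brain tumor 1, was 0.996 to 1.002 in human and 0.998 to 1.003 in mouse libraries. The implied gene length had a median of 916 bases in human and 1554 in mouse genes. Because the lengths are defined in an unknown way, RPKM of different genes are not closely compared. Depth was 2445904 to 8419288 human reads and 231156 to 8636094 mouse reads per library, lowest for mouse in lung tumor 1.

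Genes with an RPKM of 1 or more in at least 2 libraries were tested, 14423 human and 15431 mouse genes. Log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with 1 coefficient, brain minus lung, and eBayes with an intensity trend. P-values were from moderated tests of both directions with Benjamini-Hochberg adjustment within each species, and genes with an adjusted p under 0.05 were called. The residual degrees of freedom were 3, and 8.36 in human and 5.90 in mouse genes after eBayes. An exact permutation of 3 against 2 libraries cannot give a p under 0.2 counting both directions and was not used. RPKM are given as mean ± SD for the 3 brain tumors and as mean ± SD or single values for the 2 lung tumors. Scaling was left as deposited. Replicate numbers were not used as a block, since nothing in the labels pairs a brain with a lung tumor.

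Gene lists of cell types and pathways, were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested (28 human and 35 mouse lists), with adjustment over the lists of a species. Members past the per-gene test were also counted adjusted over the list alone. Camera with an estimated correlation and fry were run on the same lists. The human lists were neuron structure and synapse, GABA and glutamate signalling, neural progenitors, astrocytes, oligodendrocytes and myelin, lung epithelial identity, epithelial junctions and keratins, mesenchymal genes, collagens and matrix, matrix proteases, reported brain metastasis mediators, proliferation, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, amino acid and integrated stress response, interferon response, antigen presentation, NF-kB targets and cytokines, ERBB ligands and receptors, Wnt and Notch, xenobiotic and NRF2 genes, immediate early genes, ribosomal proteins, mitochondrially encoded genes, endothelial and mural markers, and blood and immune markers. The mouse lists covered the cell types of brain, lung, blood and connective tissue and states such as proliferation and hypoxia.

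Genes were named by rule. In each species these were the 12 higher and 12 lower called genes with the largest log2 fold change, no overlap between groups and a mean RPKM of at least 5 in the higher group, leaving out predicted genes, pseudogenes and clone names. For each list up to 4 called members were named by largest log2 fold change, or, with 0 called, the 2 members with the highest mean RPKM. Neural, blood and vessel markers whose mouse gene was among the 5 most abundant of its list were given in both tables. Human genes picked outside the rule are said to be so. The model, the threshold, the lists, the naming rule and the first settings to vary were fixed before the data were examined.

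Settings varied by plan were pseudocounts of 0.1 and 0.5, no filter, a filter at an RPKM of 5, median-ratio scaling, quantile normalization, eBayes without a trend or robust, the replicate number as a block, limma treat against a log2 change of 1, leaving out each library, and leaving out 495 tested human genes whose same-symbol mouse gene had over 10 times their RPKM in the human gene's higher group. Chosen after seeing the data were limma voom on recovered reads, a loess correction per library for gene length, and the share of human reads as a covariate. Genes at 0 in a whole group were also set to 3 reads per library for bounds. Groups of 3 and 2 are too small for an outlier test.

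The model was tested on simulated data of the same size and depth with 50 genes changed at each of 2-, 4-, 8- and 16-fold. It called 2%, 82%, 100% and 100% of them in the human table, with 9 of 14223 unchanged genes called, and 0%, 60%, 96% and 100% in the mouse table, with 4 of 15231. The simulation spread all libraries alike and does not carry the difference between the lung tumors seen here. Checks and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Gene positions came from a RefSeq gene table on GRCh38.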

Results

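Tumors of H2030-BrM3, a human lung adenocarcinoma line selected for growth in the brain, were profiled by RNA sequencing after growth in athymic nu/nu mice, which lack a thymus. Brain tumors gave 3 libraries and orthotopic lung tumors, seeded through the trachea per the labels, gave 2. Each library yielded values for 25524 human genes, read as the cancer cells, and for 24628 mouse genes, read as the host tissue. The number of reads behind the values was recovered from the deposited RPKM and gives the depth of each library. Human reads numbered 8419288, 6393890 and 2445904 in brain tumors 1, 2 and 3, and 6541037 and 3733689 in lung tumors 1 and 2. Mouse reads numbered 2710983, 4915553 and 8636094 in the brain tumors, but 231156 in lung tumor 1 and 5295159 in lung tumor 2. Human reads were thus 75.6%, 56.5% and 22.1% of the total in the brain tumors and 96.6% and 41.4% in the lung tumors. In lung tumor 1, 11897 mouse genes were listed at 0, against 3756 to 6122 in the other 4 libraries. The lung tumors differed from each other more than the brain tumors did. The SD over tested genes of the log2 difference between lung tumors 1 and 2 was 1.06 for human genes (brain pairs 0.454 to 0.768) and 1.57 for mouse genes (brain pairs 0.547 to 0.712). In lung tumor 1 the longest 20% of the genes lay below their gene means (medians -0.54 in human and -0.82 in mouse genes on the log2 scale), and in the other 4 libraries above them. The labels do not say that the tumors came from separate animals, so p-values measure only the spread between these samples, whatever its source.

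**Figure D1:**
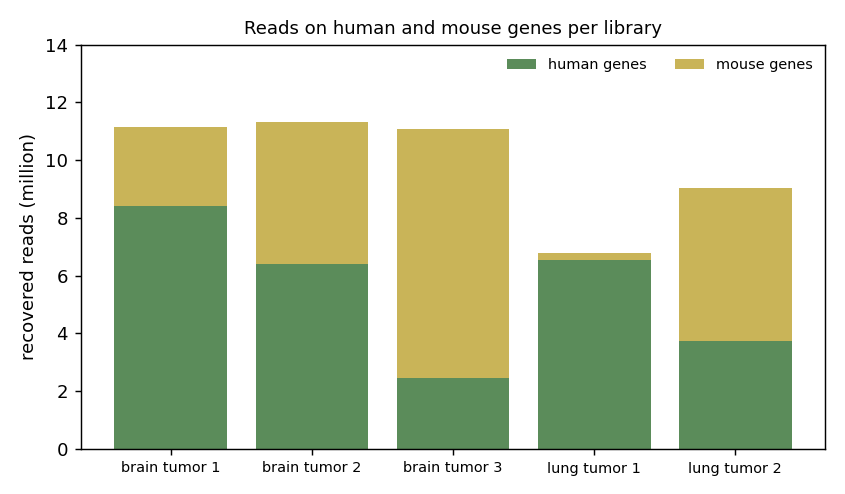
Recovered reads per library (vertical axis) for the human and mouse tables in the 3 brain and 2 lung tumors. Lung tumor 1 held 6541037 human reads but 231156 mouse reads.

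The first comparison asked how the cancer cells differed between the brain and the lung. IGFBP5, which encodes a secreted protein that binds insulin-like growth factors, was the 1 human gene that passed the test, and it rose in the brain tumors. Its level was 82.7 ± 16.2 RPKM in the brain tumors (mean ± SD, n = 3) and 2.03 ± 0.213 RPKM in the lung tumors (n = 2), with a log2 fold change of 4.77 (SE 0.37, limma adjusted p = 0.0114). All 3 brain tumors, at 83.3, 66.2 and 98.6 RPKM, lay above both lung tumors, at 1.88 and 2.18 RPKM. The gene (ENSG00000115461.4) is protein-coding and lies on chromosome 2 from 216672105 to 216695549 in GRCh38. These values rested on 517, 312 and 177 reads in the brain tumors and on 9 and 6 reads in the lung tumors. The mouse gene Igfbp5 had 58.9, 35.8 and 31.9 RPKM in the brain tumors and 5.74 and 49.6 RPKM in the lung tumors, so its levels overlapped between the groups. Of 14423 human genes tested with limma on log2(RPKM + 1), 0 fell in the brain tumors at an adjusted p under 0.05, while 1517 had an unadjusted p under 0.05 in either direction. The groups did not overlap for 4283 genes, or 29.7%, where chance gives 20%. The IGFBP5 call was lost without brain tumor 1 (adjusted p = 0.0653), brain tumor 2 (0.0587), brain tumor 3 (0.363) or lung tumor 1 (0.156), and with voom on the recovered reads (0.121) or the share of human reads as a covariate (0.113). These fits each called 0 human genes. With the replicate number as a block 114 genes passed (53.5% of them higher). That fit rests on 2 pairs, which the labels do not give, and takes nothing from brain tumor 3 for the difference. Over 19 alternatives the adjusted p of IGFBP5 ran from 5.77e-12 to 0.363 and its log2 fold change from 4.64 to 5.27. By contrast 1905 genes passed without lung tumor 2 (63.8% of them higher in the brain tumors), where the lone lung tumor is assumed to vary like the brain tumors and the median log2 fold change of all human genes was 0.25. That median was 0.09 in all 5 libraries, -0.03 with median-ratio scaling, 0.01 with quantile normalization and -0.02 with gene-length correction.

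Because 1 gene passed, the 12 human genes with the lowest unadjusted p in each direction were also picked, after their values were seen, and apart from IGFBP5 none of them passed the test (limma adjusted p from 0.293 to 0.304). MAP2, a microtubule protein of neuronal dendrites, had 604 ± 171 RPKM in the brain tumors and 82.3 ± 29.2 in the lung tumors (mean ± SD, n = 3 and n = 2 here and below; log2 fold change 2.86, SE 0.40). ABCA1, a cholesterol efflux pump, had 90.1 ± 26.7 against 12.1 ± 2.38 RPKM, and ANTXR1, an anthrax toxin receptor that binds matrix, had 60.4 ± 31.8 against 3.77 ± 2.12. The matrix glycoprotein gene SPARCL1 stood at 68.0 ± 50.4 against 3.56 ± 1.89 RPKM. The chromatin protein gene HMGA2 was at 23.6 ± 6.98 against 3.50 ± 0.108. HP, which encodes haptoglobin and shares sequence with the near-identical HPR so that its reads are uncertain, had 77.1 ± 51.6 against 5.31 ± 2.42 RPKM. The other 5 were ENTPD2, ETV1, RBMS3, TENM3 and ZFHX4, with log2 fold changes of 2.89, 1.88, 2.36, 2.80 and 3.29. Among the 12 genes with lower values in the brain tumors, the chemokine gene CCL20 had 1.27 ± 0.322 against 20.9 ± 13.8 RPKM (log2 fold change -3.12, SE 0.51), and PPBP, a platelet chemokine gene, had 0.446 ± 0.427 against 6.55 ± 1.56. IGFBP3, another binder of insulin-like growth factors, had 62.9 ± 15.99 against 214 ± 24.8 RPKM, opposite in sign to IGFBP5. The 14-3-3 protein gene SFN had 69.1 ± 23.5 against 400.4 ± 232 RPKM, and FXYD5, a regulator of the sodium pump, had 98.9 ± 24.2 against 388 ± 51.8. EEF1A2, EFHD2, FAM110B, FSTL3, LYPD3, TUBA4A and UPP1 had log2 fold changes of -2.25, -1.99, -2.50, -1.56, -2.52, -2.04 and -2.06. Without lung tumor 2, 11 of the 12 genes with higher and 10 of the 12 with lower values passed, and with the replicate block, which leaves brain tumor 3 out of the difference, 11 and 10 passed as well.

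**Figure D2:**
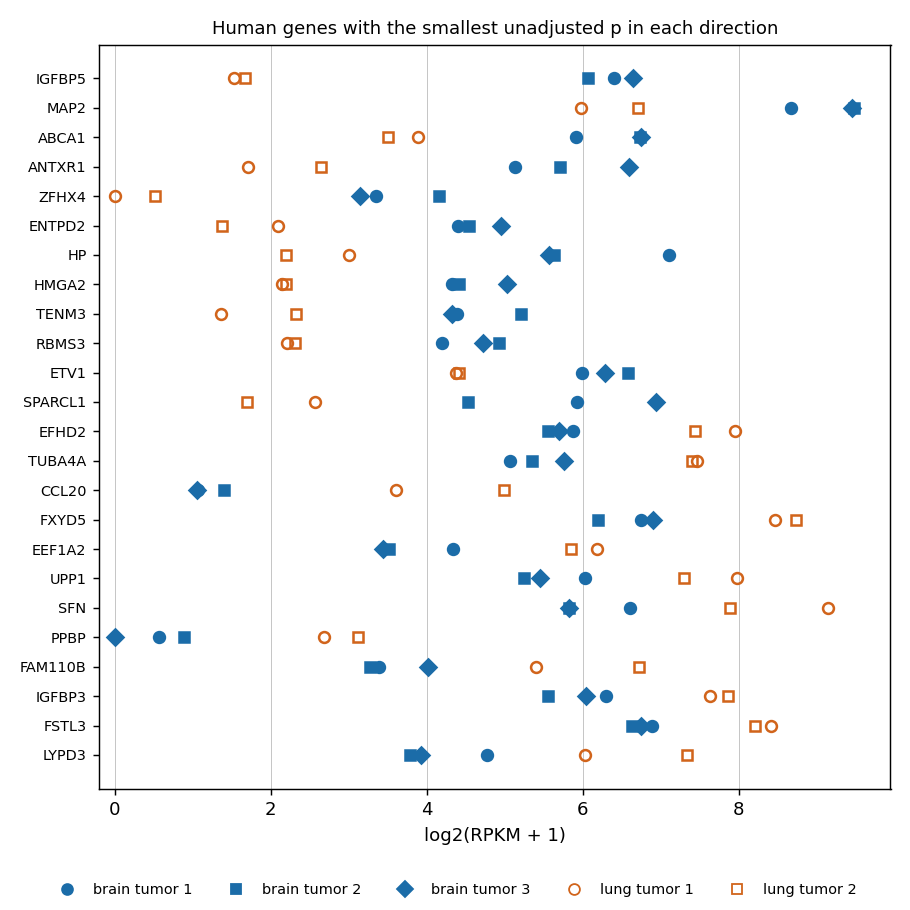
RPKM on a log axis in each of the 3 brain and 2 lung tumors for the human genes with the lowest unadjusted p. IGFBP5, the 1 gene past the test, stood at 66.2 to 98.6 RPKM in the brain tumors and at 1.88 to 2.18 in the lung tumors.

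Gene lists fixed in advance were tested against all other genes with limma's camera at a preset correlation, and 28 human lists had enough tested members. Hypoxia-induced genes fell as a group in the brain tumors (20 members, median log2 fold change -0.95, camera adjusted p = 7.9e-09, adjusted p = 0.764 with an estimated correlation), and 18 of 20 had a negative log2 fold change. CA9, a carbonic anhydrase induced by low oxygen, had 3.63 ± 5.57 RPKM in the brain and 31.3 ± 22.2 in the lung tumors, ADM, which encodes adrenomedullin, 3.54 ± 1.38 against 21.1 ± 19.2, and BNIP3, a mitophagy gene, 20.9 ± 12.5 against 68.8 ± 2.01. The members with the highest levels, ENO1 and LDHA, had 2398 ± 348 against 3353 ± 1472 and 1466 ± 276 against 2004 ± 219 RPKM. Glycolysis genes, which share ALDOA, ENO1, LDHA, PGK1, SLC2A1 and TPI1 with the hypoxia list, fell too (18 members, median log2 fold change -0.48, camera adjusted p = 0.000374, adjusted p = 0.764 with an estimated correlation). GAPDH was at 2973 ± 466 against 4513 ± 2530 RPKM and the lactate exporter gene SLC16A3 at 2.96 ± 2.86 against 43.1 ± 51.4. NF-kB targets and cytokines fell (15 members, median log2 fold change -1.14, camera adjusted p = 2.64e-05, adjusted p = 0.764 with an estimated correlation). In that list CXCL8 had 20.4 ± 12.6 against 209 ± 169.7 RPKM, CXCL2 6.88 ± 0.651 against 71.7 ± 71.7 and IL6 4.21 ± 2.70 against 29.0 ± 30.2, while the abundant members BIRC3 and NFKB1 had 224 ± 90.5 against 355 ± 269 and 134 ± 11.7 against 78.2 ± 58.2. Immediate early genes, which answer growth and stress signals within minutes, fell as well (12 members, median log2 fold change -0.84, camera adjusted p = 0.000229, adjusted p = 0.764 with an estimated correlation). JUNB was at 45.5 ± 11.5 against 111 ± 2.20 RPKM and NR4A1 at 129 ± 61.3 against 269 ± 48.6. Of these members ADM, BNIP3, CA9, CXCL2, CXCL8, IL6 and SLC16A3 were picked after their values were seen. By limma 0 members of these 4 lists passed over all genes, and 11, 4, 6 and 4 had an unadjusted p under 0.05 in the order given. Adjusted over the list alone, 7 hypoxia, 0 glycolysis, 5 NF-kB and 2 immediate early genes were lower. In every brain tumor 13 of 20 hypoxia and 6 of 18 glycolysis genes were below both lung tumors. So were 6 of 15 NF-kB and 6 of 12 immediate early genes, against 29.7% of tested human genes without overlap either way. The NF-kB median was -0.54 without lung tumor 2 (adjusted p = 0.0261, and 8.77e-10 to 0.0261 over preset-correlation alternatives). The immediate early median was -1.31 without lung tumor 1 (adjusted p = 3.01e-05), -0.56 without lung tumor 2 (adjusted p = 0.115) and -0.56 (adjusted p = 0.000398) with no filter (adjusted p 5.46e-08 to 0.115 over preset-correlation alternatives).

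Mitochondrially encoded genes, which encode subunits of the respiratory chain, rose in the brain tumors (13 members, median log2 fold change 0.72, camera adjusted p = 0.00241, adjusted p = 0.764 with an estimated correlation). MT-CO3 had 9640 ± 3459 RPKM in the brain and 6787 ± 4953 in the lung tumors, and MT-ND4 8399 ± 1904 against 5221 ± 1857; 1 of 13 members was higher when adjusted over the list alone. Nuclear genes of the same respiratory chain fell (21 members, median log2 fold change -0.65, camera adjusted p = 0.00858, adjusted p = 0.764 with an estimated correlation). COX4I1 was at 727 ± 53.0 against 1678 ± 1472 RPKM, while ATP5B was at 1221 ± 112 against 1177 ± 182. Cytosolic ribosomal protein genes fell (21 members, median log2 fold change -0.38, camera adjusted p = 0.00438, adjusted p = 0.847 with an estimated correlation). RPL8 was at 2695 ± 468 against 5239 ± 3512 RPKM. Proliferation genes rose (24 members, median log2 fold change 0.38, camera adjusted p = 0.0235, adjusted p = 0.764 with an estimated correlation). Of them 11 were higher in every brain tumor than in both lung tumors, against 29.7% of tested human genes without overlap either way. TOP2A, the topoisomerase that untangles DNA before division, had 1013 ± 28.9 against 525 ± 436 RPKM and RRM2, which makes deoxynucleotides, 566 ± 142 against 448 ± 279. Fatty acid synthesis genes rose (12 members, median log2 fold change 0.53, camera adjusted p = 0.0310, adjusted p = 0.764 with an estimated correlation). The regulator SREBF1 was at 513 ± 90.6 against 360.4 ± 84.0 and FADS2 at 485 ± 215 against 367 ± 84.1 RPKM. Amino acid and stress response genes fell (17 members, median log2 fold change -0.48, camera adjusted p = 0.00858, adjusted p = 0.764 with an estimated correlation). The transporter subunit SLC3A2 was at 369.5 ± 48.5 against 546 ± 65.7 and MTHFD2 at 234 ± 99.2 against 291 ± 92.1 RPKM. Antigen presentation genes fell (11 members, median log2 fold change -0.40, camera adjusted p = 0.0438, adjusted p = 0.764 with an estimated correlation). B2M was at 193 ± 64.3 against 264 ± 185 RPKM. By limma 0 members of these 7 lists passed over all genes, against unadjusted p under 0.05 for 4 mitochondrially encoded, 0 nuclear respiratory chain, 0 ribosomal, 4 proliferation, 2 fatty acid, 5 stress response and 2 antigen presentation genes, and adjusted over the list alone 0 passed in all but the first. In all, 11 of 28 human lists passed camera with its preset correlation (3 higher, 8 lower), 0 with an estimated correlation (1 list at an unadjusted p under 0.05), and 0 in fry (4 lists at an unadjusted p under 0.05), which tests whether a list's genes move on balance one way. These 7 calls depended on single libraries. Mitochondrially encoded genes had a median of 0.89 without lung tumor 2 (adjusted p = 0.172). Proliferation genes had 0.31 without brain tumor 1 (adjusted p = 0.0944), 0.32 without brain tumor 3 (adjusted p = 0.120) and 0.23 without lung tumor 1 (adjusted p = 0.0513). Nuclear respiratory chain genes had 0.13 without lung tumor 1 (adjusted p = 0.145) and -1.13 without lung tumor 2 (adjusted p = 2.55e-07). Ribosomal protein genes had 0.37 without lung tumor 1 (adjusted p = 4.07e-05) and -1.25 without lung tumor 2 (adjusted p = 4.33e-14). Fatty acid synthesis genes had 0.57 without brain tumor 1 (adjusted p = 0.113), 0.11 without lung tumor 1 (adjusted p = 0.294) and 0.96 without lung tumor 2 (adjusted p = 0.0163). Stress response genes had -0.31 without brain tumor 2 (adjusted p = 0.102) and -0.24 without lung tumor 2 (adjusted p = 0.358). Antigen presentation genes had -0.31 without brain tumor 2 (adjusted p = 0.269), -0.84 without lung tumor 1 (adjusted p = 0.000447) and -0.40 without lung tumor 2 (adjusted p = 0.913). Over preset-correlation alternatives the adjusted p ran from 5.54e-06 to 0.172 for mitochondrially encoded, 0.00641 to 0.161 for proliferation, 2.55e-07 to 0.145 for nuclear respiratory chain, 4.33e-14 to 0.269 for ribosomal, 0.00360 to 0.294 for fatty acid, 0.000927 to 0.358 for stress response and 0.000447 to 0.913 for antigen presentation genes. Proliferation lost its call with median-ratio scaling, at 0.25 (adjusted p = 0.0512), and with the replicate block, at 0.32 (adjusted p = 0.161), the median without brain tumor 3. Antigen presentation lost its call with median-ratio scaling, at -0.53 (adjusted p = 0.0512), with voom, at -0.46 (adjusted p = 0.0741), with gene-length correction, at -0.45 (adjusted p = 0.0661), and with wrong-species candidates left out, at -0.35 (adjusted p = 0.0712). With quantile normalization nuclear respiratory chain genes lost theirs at -0.59 (adjusted p = 0.0995) and ribosomal protein genes at -0.12 (adjusted p = 0.269). Both also lost their calls with the share of human reads as a covariate, at -0.37 (adjusted p = 0.137) and -0.18 (adjusted p = 0.144), and the proliferation median was 0.25 (adjusted p = 0.0312) there.

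**Figure D3:**
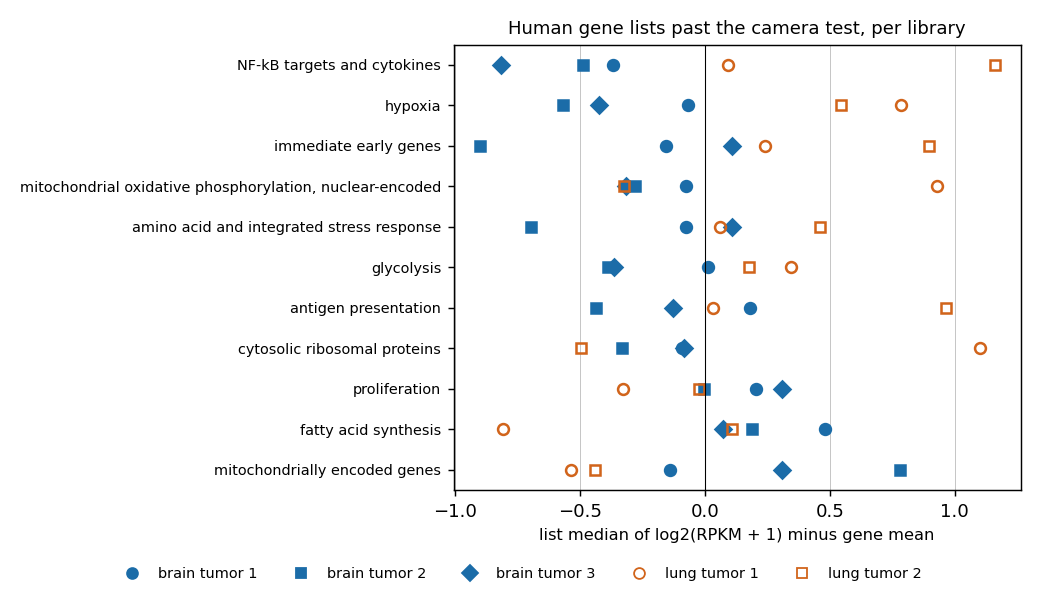
Median over each list's members of log2(RPKM + 1) minus the gene's mean over the 5 libraries (horizontal axis), for the 11 human lists past the camera test, with 1 point per brain or lung tumor. The hypoxia list lay at -0.07, -0.57 and -0.42 in brain tumors 1, 2 and 3 and at 0.78 and 0.55 in lung tumors 1 and 2.

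The remaining 17 human lists did not pass camera, among them those for neural and lung identity. Of 22 neuron structure and synapse genes 8 were tested, and MAP2 at 604 ± 171 RPKM in the brain and 82.3 ± 29.2 in the lung tumors stood beside UCHL1 at 329 ± 36.3 and 441 ± 213; the median log2 fold change was -0.04 (adjusted p = 0.776). The medians were -0.12 (adjusted p = 0.520) for GABA and glutamate signalling, 0.14 (adjusted p = 0.870) for neural progenitor genes, 0.09 (adjusted p = 0.776) for astrocyte markers and 0.07 (adjusted p = 0.941) for oligodendrocyte and myelin markers. LHX2, a homeobox gene, had 29.0 ± 14.4 against 24.4 ± 2.90 RPKM and MSI1, which encodes an RNA-binding protein, 12.9 ± 4.77 against 12.6 ± 2.30. Lung epithelial identity genes had a median of -0.28 (adjusted p = 0.776), with MUC1 at 321 ± 48.2 against 589 ± 465. FOXA1 was at 34.9 ± 8.56 against 33.2 ± 33.3 RPKM. Epithelial junction and keratin genes had -0.36 (adjusted p = 0.333), with KRT8 at 744 ± 519 against 869 ± 52.5. KRT18 was at 350.4 ± 219.9 against 405 ± 90.3 RPKM. Mesenchymal genes had 0.22 (adjusted p = 0.941), or 0.16 with CDH2, at 0 in both lung tumors, set to 3 reads per library; VIM stood at 809.9 ± 172 against 658 ± 121 RPKM. The tenascin C gene TNC was at 704 ± 188 against 221 ± 143. Collagens and matrix had -0.27 (adjusted p = 0.776), matrix proteases -0.35 (adjusted p = 0.179) and reported brain metastasis mediators -0.00376 (adjusted p = 0.884). COL1A1 had 153 ± 60.0 against 286 ± 314 RPKM, LAMA3 63.0 ± 27.6 against 352 ± 409, TIMP1 1642 ± 1192 against 2819 ± 1089, MMP14 1407 ± 92.2 against 1680 ± 641, FSCN1 394 ± 2.69 against 428 ± 96.2 and ANGPTL4 175 ± 104 against 740.2 ± 379. Cholesterol synthesis genes had 0.02 (adjusted p = 0.631), interferon response 0.03 (adjusted p = 0.818), ERBB ligands and receptors 0.12 (adjusted p = 0.882), Wnt and Notch genes -0.04 (adjusted p = 0.776), xenobiotic and NRF2 genes 0.36 (adjusted p = 0.333) and endothelial and mural markers 0.57 (adjusted p = 0.618). For these FDPS stood at 278 ± 54.4 against 435 ± 51.8 RPKM and STARD4 at 301 ± 17.2 against 168 ± 103. IFI6 was at 377 ± 356 against 792 ± 991. ISG15 was at 109.9 ± 102 against 220.4 ± 194 and AREG at 68.1 ± 70.2 against 431 ± 315. ERBB2 was at 96.5 ± 7.92 against 51.8 ± 2.71. NOTCH3 was at 199.9 ± 34.9 against 93.5 ± 21.6 and JAG2 at 38.8 ± 3.97 against 92.2 ± 17.7. NQO1 was at 3017 ± 402 against 2806 ± 1959. TXNRD1 was at 1836 ± 684 against 1387 ± 412 and TAGLN at 28.9 ± 12.9 against 18.6 ± 6.58. The medians of the cholesterol and interferon lists were negative with median-ratio scaling, quantile normalization and gene-length correction, those of the astrocyte and oligodendrocyte lists with median-ratio scaling, and those of the astrocyte, progenitor and ERBB lists with gene-length correction. With 1 library left out the sign turned in 13 of the 17 lists, all but the junction, protease, xenobiotic and endothelial lists. Lung epithelial identity had -0.57 without lung tumor 1 and 0.60 without lung tumor 2, mediators -0.46 without lung tumor 1 and 0.54 without lung tumor 2. Of the blood and immune cell markers 0 reached the level needed for testing. The sign of the median, the mean and the test differed for the neuron (mean 0.37), mesenchymal (0.10), collagen (0.09), cholesterol (-0.03), interferon (0.06), ERBB (-0.34) and Wnt and Notch lists (0.23), where camera leaned higher for the neuron and the Wnt and Notch lists and lower for the other 5. By limma 0 members of the 17 lists passed over all genes. Adjusted over the list alone, 2 neuron genes were higher, 2 astrocyte genes higher and 1 lower, 1 mesenchymal gene higher and 1 lower, 3 matrix genes higher, 1 protease list gene higher and 2 lower, 3 mediators higher and 2 lower, 2 ERBB genes lower, and 1 Wnt and Notch gene higher and 1 lower. Unadjusted p under 0.05 held for 2, 3, 7, 5, 5, 5, 4 and 4 members of these 8 lists, for 2 cholesterol genes, for 1 junction, 1 xenobiotic and 1 endothelial gene, and for 0 in the other 5 lists. The protease list had a median of -0.60 without lung tumor 1 but -0.05 without lung tumor 2, so its size rested on the lung tumor kept. Interferon response genes took opposite signs, -1.25 without lung tumor 1 (adjusted p = 4.96e-06) and 1.33 without lung tumor 2 (adjusted p = 0.0220, and 4.96e-06 to 0.997 over preset-correlation alternatives).

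Marker genes measured in both tables showed how far the species were kept apart. Gfap, the astrocyte filament gene, had 18185, 24666 and 30798 mouse reads in brain tumors 1, 2 and 3, and the human GFAP was listed at 0, 2.37 and 0 RPKM there. The glutamate transporter gene Slc1a2 had 11573, 25702 and 36718 mouse reads there, against 0 human SLC1A2 reads in each. Mobp, a myelin gene, had 6279, 5678 and 11861 mouse reads, and human MOBP was listed at 0, 0 and 0.482 RPKM. For GFAP and MOBP, each above 0 in 1 library, the number of reads is not fixed. Snap25 had 3974, 7472 and 19909 mouse reads, against 10, 21 and 16 of human SNAP25, and Mapt 927, 1839 and 3198, against 9, 8 and 4 of MAPT. Human CSF1R had 0, 0 and 1 reads, CD68 0, 3 and 0 and CD14 1, 3 and 0 where mouse Csf1r, a macrophage receptor gene, had 1543, 2806 and 1895. Other symbols had reads in both tables. Human CLU, CST3, UCHL1, CNP and MBP had 874, 290.0, 290.3, 353 and 234 RPKM in lung tumor 2, where the mouse genes had 569.5, 1180, 7.04, 23.8 and 29.4. SYP, ESAM, RGS5, TAGLN and ACTA2 had 16.2, 1.27, 1.80, 18.7 and 18.7 human RPKM in brain tumor 1, against 1670, 95.4, 176, 16.6 and 15.6 of the mouse genes. Human ALDOC had 27.04, 6.90 and 12.4 RPKM in the brain tumors, where mouse Aldoc had 2726, 1848 and 2574. MAP2 was abundant in both species in the brain tumors, at 406, 708 and 697 human and 634, 950.0 and 515 mouse RPKM, and human SPARCL1 (60.0, 22.1 and 122) met mouse Sparcl1 at 1999, 1646 and 1626 RPKM. Of the tested human genes, 495 had a same-symbol mouse gene at over 10 times their RPKM where the human gene was higher, a ratio across unlike scales. Leaving those out kept the IGFBP5 call and left 3 astrocyte markers, with a median of -1.05 (adjusted p = 0.0328, and 0.0328 to 0.883 over preset-correlation alternatives). That rule favours dropping markers higher in the brain, where mouse astrocyte genes abound, so this sign decides nothing.

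The second comparison asked how the host tissue of brain tumors differed from that of lung tumors, and it set 2 organs with different cell types side by side, not tissue with and without a tumor. Genes of neurons and glia rose in the brain tumors. Scg5, a neuroendocrine secretory protein gene, had 454 ± 57.8 RPKM in the brain tumors (mean ± SD, n = 3) and 0 and 1.03 in the lung tumors (n = 2; log2 fold change 8.31, SE 0.39, limma adjusted p = 0.00112). The astrocyte gene Gfap had 1917 ± 589.6 against 24.3 and 0.782 RPKM (log2 fold change 8.11, SE 1.08), and the kinase gene Camk2a of excitatory neurons 1018 ± 353 against 4.86 and 2.35. Nrsn1 and Caln1, at 226 ± 6.02 and 176 ± 83.4 RPKM in the brain tumors, were listed at 0 in both lung tumors. Mobp, S100b, Slc6a11, Snap25, Stmn3 and Unc80 were also among the 12 genes with the highest log2 fold change, from 7.31 to 8.31 as fitted, which is no bound for Nrsn1 and Caln1, and all 12 passed without any single library. Genes of lung epithelium and of blood and myeloid cells fell in the brain tumors. Sftpc, a surfactant protein gene, had 4.93 ± 3.28 RPKM in the brain and 152 and 14030 in the lung tumors, and Scgb1a1, the club cell secretory protein gene, 28.2 ± 17.8 against 708 and 44860. Saa3, an acute phase gene, had 8.83 ± 2.73 against 12170 and 671 RPKM (log2 fold change -8.22, SE 1.16, limma adjusted p = 0.00655), Arg1, the arginase of activated macrophages, 0.699 ± 0.0300 against 1271 and 93.8, and Cbr2 6.22 ± 3.65 against 887 and 4076. Ces1d, Hba-a2, Hp, Igkc, Krt19, Marco and Sftpb completed the 12 with the lowest log2 fold change, from -8.22 to -7.03, with limma adjusted p from 0.00126 to 0.0376. In total 3457 of 15431 mouse genes passed (2204 higher and 1253 lower in the brain tumors, 63.8% higher), and 5940 had an unadjusted p under 0.05. The groups did not overlap for 56.1% of genes, where chance gives 20%. Among the 12 lower genes, calls ended for Saa3 without brain tumor 3 and for Sftpc, Scgb1a1, Marco, Ces1d and Sftpb without brain tumor 1, 2 or 3. There their adjusted p ran from 0.0520 to 0.149, and over all their alternatives from 0.000921 to 0.149. The count was 1518, 1195 and 1294 without brain tumor 1, 2 or 3 (73.8%, 84.7% and 81.1% higher), and 4591 and 8275 without lung tumor 1 or 2, with 54.0% and 62.1% of them higher. It was 2295 with no filter on low values. With quantile normalization, gene-length correction or voom on the recovered reads, 54.0%, 57.4% and 50.7% of the called genes were higher, and the median of all mouse genes moved from 0.08 to -0.11, -0.06 and -0.15, against 0.21 with median-ratio scaling.

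Lists of neuron, astrocyte, oligodendrocyte, progenitor and brain endothelial genes rose in the brain tumors. Neuron markers had 18 of 20 members higher (median log2 fold change 5.66, camera adjusted p = 3.76e-12, adjusted p = 0.137 with an estimated correlation). The GABA-synthesizing enzyme gene Gad1 was at 244 ± 79.4 RPKM against 2.90 and 0.382 in the lung tumors and Syt1, a synaptic vesicle gene, at 291 ± 79.3 against 6.41 and 0.562. Snap25 was at 816 ± 218 against 11.9 and 0.786. Astrocyte markers had 14 of 15 members higher (median log2 fold change 5.27, camera adjusted p = 1.25e-10, adjusted p = 0.238 with an estimated correlation). Slc1a2 was at 8325 ± 1018 against 86.1 and 36.7 and S100b at 216 ± 61.7 against 0 and 0.623. Ntsr2 was at 115 ± 14.8 against 0 and 0.119 RPKM. All 14 oligodendrocyte and myelin markers were higher (median log2 fold change 4.76, camera adjusted p = 2.21e-09, adjusted p = 0.278 with an estimated correlation). Mobp was at 543 ± 207 against 2.90 and 0.509 and Cldn11 at 160.1 ± 51.5 against 2.25 and 0.297. Mag was at 107 ± 37.1 against 0 and 1.93 RPKM. Oligodendrocyte progenitor markers rose with 5 of 9 members (median log2 fold change 2.54, camera adjusted p = 0.0186, adjusted p = 0.446 with an estimated correlation). Bcas1 was at 174 ± 56.1 against 0 and 4.74 and Tnr at 225 ± 64.2 against 5.04 and 1.32. Lhfpl3 was at 16.9 ± 1.15 against 1.48 and 0. C1ql1 was at 7.59 ± 1.74 against 0 and 0.251 RPKM. Brain endothelial and barrier genes rose with 3 of 14 (median log2 fold change 1.07, camera adjusted p = 0.0159, adjusted p = 0.446 with an estimated correlation). These 3 were transporter genes of the blood-brain barrier, Slco1c1 at 18.4 ± 5.74 against 0 and 0.142 RPKM and Slco1a4 and Slc22a8 at 30.1 ± 10.3 and 4.02 ± 1.33, both listed at 0 in the lung tumors, where 3 reads per library would give log2 fold changes of 2.88 and 1.07. With members at 0 in both lung tumors set to 3 reads per library, the barrier list's median was 1.04 and the medians of the neuron, myelin and progenitor lists were 5.66, 4.76 and 2.54 as before. In the myelin list Olig2 and Opalin were listed at 0 in both lung tumors. With 3 reads per library there, their bounds fell below 0 and were set to 0, so their rise is not shown beyond that floor. Pan-reactive astrocyte genes fell (median log2 fold change -1.21, camera adjusted p = 0.0424, adjusted p = 0.446 with an estimated correlation) but did not pass fry (adjusted p = 0.1306). Of the 13 members 2 rose, Gfap and the asparaginase gene Aspg at 28.4 ± 4.31 against 1.54 and 6.16 RPKM. The 3 that fell included the protease inhibitor gene Timp1 at 20.9 ± 19.4 against 1302 and 147. Steap4 was at 1.65 ± 1.11 against 32.1 and 28.9 RPKM. Adjusted over the list alone the counts were 20 higher and 0 lower for neuron, 14 higher and 0 lower for astrocyte, 14 higher and 0 lower for myelin, 6 higher and 1 lower for progenitor, 4 higher and 0 lower for barrier and 2 higher and 3 lower for pan-reactive genes. The progenitor median was 2.56 without lung tumor 2 (adjusted p = 0.0686) and 2.73 (adjusted p = 0.0605) with the filter at an RPKM of 5. It was 5.33 (adjusted p = 0.0293) with a pseudocount of 0.1 and 5.13 (adjusted p = 0.0240) with voom on the recovered reads (adjusted p 0.00467 to 0.0686 over preset-correlation alternatives). The barrier median was 1.19 without lung tumor 1 (adjusted p = 0.0513), 2.13 without lung tumor 2 (adjusted p = 0.00578) and 1.01 (adjusted p = 0.0502) with that filter, and with that pseudocount 2.03 (adjusted p = 0.0126, and 0.00471 to 0.0513 over preset-correlation alternatives). The pan-reactive median was -1.01 without brain tumor 3 (adjusted p = 0.0559), -1.18 without lung tumor 1 (adjusted p = 0.242) and -1.07 without lung tumor 2 (adjusted p = 0.0612), and with quantile normalization -1.18 (adjusted p = 0.106). Its call also ended at -1.01 (adjusted p = 0.0594) with the replicate block, the median without brain tumor 3, and at -1.27 (adjusted p = 0.0761) with voom, -1.42 (adjusted p = 0.0572) with gene-length correction, -1.05 (adjusted p = 0.0676) with the share of human reads as a covariate and -1.21 (adjusted p = 0.0526) with the filter at an RPKM of 5 (adjusted p 0.0188 to 0.242 over preset-correlation alternatives). Calls of single genes ended for Lhfpl3 without brain tumor 2, for Slc22a8 and Aspg without brain tumor 1, 2 or 3 and for Timp1 without brain tumor 1, 2 or 3 or lung tumor 1. Their adjusted p ran from 0.0507 to 0.130 in these fits and over all their alternatives from 0.00195 to 0.130.

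Lists of lung cell types other than airway cells fell in the brain tumors by camera at its preset correlation, but did not pass fry. The fry adjusted p was 0.1534 for alveolar type 2, 0.1306 for type 1, 0.1035 for lung endothelial and 0.2035 for pan-endothelial genes. The medians of the alveolar and endothelial lists stood higher in lung tumor 2 than in lung tumor 1. Alveolar type 2 markers had 5 of 11 members lower (median log2 fold change -5.90, camera adjusted p = 0.000318, adjusted p = 0.446 with an estimated correlation). The surfactant genes Sftpb and Sftpa1 had 1.36 ± 0.190 and 0.812 ± 0.462 RPKM in the brain tumors, against 36.2 and 2557 and against 22.8 and 1584 in lung tumors 1 and 2, and the lysozyme gene Lyz1, which has a near-identical copy and is uncertain for that reason, had 0.980 ± 0.999 against 16.7 and 776. Alveolar type 1 markers had 6 of 11 lower (median log2 fold change -3.13, camera adjusted p = 0.000249, adjusted p = 0.446 with an estimated correlation). Ager was at 1.65 ± 0.369 against 28.9 and 1198 and the water channel gene Aqp5 at 0.0970 ± 0.0845 against 8.64 and 176. Emp2 was at 9.38 ± 3.50 against 56.4 and 412 and Krt7 at 0.806 ± 0.345 against 44.3 and 491 RPKM. Lung endothelial genes fell (median log2 fold change -2.88, camera adjusted p = 0.000956, adjusted p = 0.446 with an estimated correlation) with 1 of 12 members past the per-gene test, Gpihbp1, which anchors lipoprotein lipase to capillaries, at 0.828 ± 0.561 against 108 and 155 RPKM. Pan-endothelial markers fell (median log2 fold change -1.91, camera adjusted p = 0.00179, adjusted p = 0.488 with an estimated correlation) with 2 of 13, Esam at 67.6 ± 25.9 against 208 and 407. Emcn was at 7.73 ± 4.53 against 34.2 and 31.7 RPKM. Airway club and ciliated cell markers did not pass (median log2 fold change -0.56, camera adjusted p = 0.113, adjusted p = 0.690 with an estimated correlation), with 1 of 10 members lower, Scgb1a1. Counts adjusted over the list alone were 0 higher and 8 lower for type 2, 0 higher and 6 lower for type 1, 0 higher and 1 lower for airway, 0 higher and 1 lower for lung endothelial and 0 higher and 1 lower for pan-endothelial genes. The type 2 median was -2.54 without lung tumor 2 (adjusted p = 0.00170, and 1.31e-08 to 0.00170 over preset-correlation alternatives). The type 1 median was -4.87 without lung tumor 1 (adjusted p = 1.42e-07, and 1.42e-07 to 0.00864 over preset-correlation alternatives). Airway markers had -2.63 without lung tumor 1 (adjusted p = 0.000108) and turned to 1.21 without lung tumor 2 (adjusted p = 0.843). They also passed at -2.79 (adjusted p = 0.00326) with voom on the recovered reads, -0.68 (adjusted p = 0.0249) with no filter and -1.23 (adjusted p = 0.0310) with the share of human reads as a covariate (adjusted p 0.000108 to 0.843 over preset-correlation alternatives). Lung endothelial genes had -5.09 without lung tumor 1 (adjusted p = 4.72e-07), -0.84 without lung tumor 2 (adjusted p = 0.0640) and -4.36 (adjusted p = 7.73e-05) with voom (adjusted p 4.72e-07 to 0.0640 over preset-correlation alternatives). Pan-endothelial markers had -2.91 without lung tumor 1 (adjusted p = 1.59e-05) and -0.38 without lung tumor 2 (adjusted p = 0.121, and 1.59e-05 to 0.121 over preset-correlation alternatives). Single-gene calls were lost for Sftpb, Sftpa1, Lyz1, Ager, Aqp5, Emp2, Esam and Scgb1a1 without brain tumor 1, 2 or 3, for Krt7 without brain tumor 3 and for Emcn without brain tumor 1, 2 or 3 or lung tumor 1. There their adjusted p ran from 0.0527 to 0.160, and over all their alternatives from 0.000921 to 0.241.

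Immune cell lists other than homeostatic microglia fell in the brain tumors. Neutrophil genes had 7 of 10 members lower (median log2 fold change -2.95, camera adjusted p = 1.4e-05, adjusted p = 0.238 with an estimated correlation). The calcium-binding alarmin gene S100a8 was at 1.85 ± 0.811 RPKM against 146 and 112 in the lung tumors and S100a9 at 4.53 ± 2.76 against 286 and 225. Retnlg was at 0.762 ± 0.680 against 83.2 and 28.0 and the gelatinase gene Mmp9 at 4.76 ± 3.06 against 191 and 37.5. Alveolar and monocyte-derived macrophage genes had 6 of 13 lower (median log2 fold change -2.15, camera adjusted p = 0.000134, adjusted p = 0.336 with an estimated correlation). The scavenger receptor gene Marco was at 0.881 ± 1.15 against 3210 and 29.2 and Chil3 at 5.93 ± 6.28 against 140.1 and 506. Plac8 was at 2.43 ± 3.39 against 369.7 and 102. The monocyte chemokine receptor gene Ccr2 was at 1.58 ± 2.10 against 20.7 and 24.7 RPKM. B and plasma cell genes had 7 of 9 lower (median log2 fold change -3.77, camera adjusted p = 6.83e-05, adjusted p = 0.357 with an estimated correlation). The antibody chain gene Igkc was at 2.88 ± 3.97 against 586 and 908 and Ighm at 9.09 ± 5.82 against 89.8 and 442. Jchain was at 0.365 ± 0.191 against 13.6 and 46.5 and Sdc1 at 5.49 ± 3.38 against 246 and 270.1 RPKM. T and NK cell genes had 2 of 5 lower (median log2 fold change -1.97, camera adjusted p = 0.0186, adjusted p = 0.278 with an estimated correlation), the granzyme gene Gzma at 0.317 ± 0.442 against 4.80 and 53.3. Lck was at 1.59 ± 1.61 against 12.2 and 17.9 RPKM. Dendritic cell and MHC class II genes had 1 of 8 lower (median log2 fold change -3.37, camera adjusted p = 0.0384, adjusted p = 0.504 with an estimated correlation), Cd74, the invariant chain, at 34.8 ± 45.5 against 291 and 1768 RPKM. Disease-associated microglia and phagocyte genes had 2 of 17 lower (median log2 fold change -1.0, camera adjusted p = 0.0186, adjusted p = 0.488 with an estimated correlation), the galectin gene Lgals3 at 34.0 ± 15.8 against 1700 and 169. The lipase gene Lpl was at 21.4 ± 4.04 against 164 and 81.3 RPKM. Homeostatic microglia genes did not pass (median log2 fold change 0.44, camera adjusted p = 0.458, adjusted p = 0.833 with an estimated correlation). Of their 13 members the microglial factor gene Sall1, at 7.58 ± 4.88 against 0 and 0.281 RPKM, and the fructose transporter gene Slc2a5, at 3.87 ± 2.28 and listed at 0 in both lung tumors (a log2 fold change of 0 with 3 reads per library there), rose, and Olfml3, at 9.13 ± 6.46 against 85.1 and 77.4, fell. Adjusted over the list alone the counts were 0 higher and 8 lower for neutrophil, 0 higher and 8 lower for macrophage, 0 higher and 7 lower for B and plasma cell, 0 higher and 2 lower for T and NK cell, 0 higher and 5 lower for dendritic cell, 0 higher and 1 lower for phagocyte and 2 higher and 1 lower for homeostatic microglia genes. With genes at 0 in 1 group set to 3 reads per library, the homeostatic microglia median was 0.40 and the B and plasma cell median stayed at -3.77. T and NK cell genes had a median of -3.03 without lung tumor 1 (adjusted p = 0.0231) and -2.19 without lung tumor 2 (adjusted p = 0.0619, and 0.000333 to 0.0619 over preset-correlation alternatives). B and plasma cell genes had -2.29 (adjusted p = 2.8e-06) with no filter and -5.91 (adjusted p = 1.36e-05) with voom (adjusted p 2.8e-06 to 0.00400 over preset-correlation alternatives). With voom neutrophil genes had -4.67 (adjusted p = 7.52e-05) and T and NK cell genes -3.69 (adjusted p = 0.0140), and the neutrophil adjusted p ran from 4.16e-06 to 0.000360 over preset-correlation alternatives. Dendritic cell genes had -1.93 without lung tumor 2 (adjusted p = 0.278), -3.25 (adjusted p = 0.0527) with gene-length correction and -3.46 (adjusted p = 0.0536) with the share of human reads as a covariate. Their median was -1.52 (adjusted p = 0.00309) with no filter and -5.12 (adjusted p = 0.00988) with voom (adjusted p 0.00309 to 0.278 over preset-correlation alternatives). Phagocyte genes had -0.61 without brain tumor 3 (adjusted p = 0.0668), -0.56 without lung tumor 1 (adjusted p = 0.544) and -2.21 without lung tumor 2 (adjusted p = 0.000845), and with quantile normalization -0.70 (adjusted p = 0.0916). They had -1.13 (adjusted p = 0.0510) with gene-length correction and -0.76 (adjusted p = 0.0507) with the share covariate, and passed at -0.61 (adjusted p = 0.0236) with the replicate block (adjusted p 0.000845 to 0.544 over preset-correlation alternatives). Homeostatic microglia genes passed at 1.55 without brain tumor 3 (adjusted p = 0.0152) and, since the replicate block leaves the same library out of the difference, at the same median with it (adjusted p = 0.0256; adjusted p 0.0152 to 0.821 over preset-correlation alternatives). Single-gene calls ended for Mmp9, Marco, Gzma, Lgals3 and Lpl without brain tumor 1, 2 or 3, for Chil3 without brain tumor 2, for Ccr2 and Ighm without brain tumor 2 or 3, for Lck without brain tumor 1 or 3, for Cd74 without brain tumor 2 or 3 or lung tumor 2, for Sall1 without brain tumor 1 or 2 or lung tumor 1, for Slc2a5 without brain tumor 1 or 2 or lung tumor 1 or 2 and for Olfml3 without brain tumor 2 or lung tumor 1. Their adjusted p ran up to 0.149 in these fits and over all their alternatives from 0.00116 to 0.232.

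Genes of inflammation and antigen display fell with them. MHC class I and antigen processing had 9 of 11 members lower (median log2 fold change -2.55, camera adjusted p = 7.56e-06, adjusted p = 0.383 with an estimated correlation). H2-K1, whose reads can be shared with other class I genes, was at 156 ± 94.1 RPKM against 1438 and 1251. H2-T23 was at 12.2 ± 4.51 against 86.4 and 98.0. The immunoproteasome gene Psmb8 was at 8.38 ± 4.99 against 122 and 72.6 and Psmb9 at 7.01 ± 5.36 against 75.7 and 108. Interferon response genes had 8 of 23 lower (median log2 fold change -1.46, camera adjusted p = 0.000116, adjusted p = 0.446 with an estimated correlation). Ifitm3 was at 79.6 ± 30.7 against 1013 and 575 and Bst2 at 29.4 ± 17.4 against 309 and 149.8. Isg15 was at 6.58 ± 4.05 against 50.2 and 50.4. Oas2 was at 0.652 ± 0.590 against 5.40 and 15.8 RPKM. Complement genes had 7 of 13 lower (median log2 fold change -3.40, camera adjusted p = 3.71e-05, adjusted p = 0.357 with an estimated correlation). C3, the central component, was at 51.1 ± 32.6 against 1449 and 3718 and C1s1 at 8.61 ± 6.25 against 436 and 388. The inhibitor gene Serping1 was at 35.2 ± 11.8 against 539 and 423 and Cfp at 8.13 ± 1.29 against 517 and 83.9 RPKM. Chemokines and inflammatory cytokines had 8 of 19 lower and 1 higher (median log2 fold change -2.65, camera adjusted p = 0.000116, adjusted p = 0.278 with an estimated correlation). The lower ones included Ccl6 at 22.8 ± 17.1 against 3655 and 430.5 and Ccl7 at 0.777 ± 0.886 against 153 and 9.93. Ccl9 was at 5.10 ± 4.33 against 473 and 47.6. The B cell chemokine gene Cxcl13 was at 2.29 ± 1.96 against 132 and 49.0 RPKM. Counts adjusted over the list alone were 0 higher and 10 lower for MHC class I, 0 higher and 8 lower for interferon, 0 higher and 8 lower for complement and 1 higher and 9 lower for chemokine genes. The interferon median was -0.88 without lung tumor 2 (adjusted p = 0.0146) and -2.41 (adjusted p = 1.04e-05) with voom (adjusted p 1.01e-05 to 0.0146 over preset-correlation alternatives). Calls of these genes were lost for H2-K1, Psmb8, Psmb9 and Isg15 without brain tumor 2, for Bst2, Ccl6 and Ccl9 without brain tumor 1, 2 or 3 or lung tumor 1 and for Oas2, Cfp and Ccl7 without brain tumor 1, 2 or 3. There their adjusted p ran from 0.0515 to 0.144, and over all their alternatives from 0.000999 to 0.144.

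Connective tissue genes fell in the brain tumors. Fibroblast and matrix genes had 14 of 18 members lower (median log2 fold change -4.23, camera adjusted p = 1.25e-10, adjusted p = 0.278 with an estimated correlation). Of them 17 were lower in every brain tumor than in both lung tumors, against 56.1% of tested mouse genes without overlap either way. The fibrillar collagen genes Col1a1 and Col3a1 had 176 ± 210.1 and 74.2 ± 97.5 RPKM in the brain tumors, against 10040 and 4765 and against 4244 and 3365 in lung tumors 1 and 2, with Bgn at 34.8 ± 30.4 against 1917 and 1074. Mfap5 was at 1.01 ± 0.833 against 208 and 40.5. Pericyte and smooth muscle genes had 6 of 12 lower and 1 higher (median log2 fold change -2.39, camera adjusted p = 0.00104, adjusted p = 0.387 with an estimated correlation). The contractile gene Acta2 was at 10.01 ± 4.91 against 436 and 128 and Tagln at 12.7 ± 5.22 against 454 and 124. Des was at 3.21 ± 2.10 against 576 and 124 and Higd1b at 5.12 ± 3.03 against 87.5 and 45.7 RPKM. Mesothelium and adipose genes had 5 of 7 lower (median log2 fold change -3.68, camera adjusted p = 2.27e-05, adjusted p = 0.238 with an estimated correlation). Msln was at 2.21 ± 0.547 against 59.8 and 53.5 and the transcription factor gene Wt1 at 0.0198 ± 0.0343 against 42.0 and 12.8. Krt19 was at 0.722 ± 0.916 against 205 and 222 and Cfd at 0.243 ± 0.136 against 22.8 and 9.62 RPKM. Skeletal and cardiac muscle genes had 2 of 10 lower (median log2 fold change -2.67, camera adjusted p = 0.000956, adjusted p = 0.238 with an estimated correlation), Actc1, listed at 0 in the 3 brain tumors and at 4.75 and 103 RPKM in the lung tumors, and Tnni3 at 1.31 ± 0.105 against 7.55 and 43.4. Erythroid genes had 5 of 6 lower (median log2 fold change -6.09, camera adjusted p = 0.000245, adjusted p = 0.278 with an estimated correlation). Of these Alas2 makes heme and 4 are hemoglobin genes with near-identical copies, so that the split between copies is uncertain, with Hbb-bs at 42.7 ± 57.0 against 3811 and 1528. Hbb-bt was at 2.39 ± 3.28 against 186 and 202 and Hba-a1 at 13.8 ± 15.7 against 742 and 383. Hba-a2 was at 0.325 ± 0.392 against 571 and 113 RPKM. Choroid plexus and ependyma genes did not pass (median log2 fold change 0.05, camera adjusted p = 0.605, adjusted p = 0.798 with an estimated correlation; mean -0.66, of the opposite sign to the median, which was negative with quantile normalization and gene-length correction, and camera leaned lower). Their median was -1.09 without lung tumor 1 and 0.97 without lung tumor 2. Otx2, a homeobox gene at 4.24 ± 0.644 RPKM and listed at 0 in both lung tumors (a log2 fold change of 0.06 with 3 reads per library there), rose. Those that fell were the water channel gene Aqp1 at 3.41 ± 4.40 against 49.7 and 332. Rarres2 was at 25.9 ± 11.3 against 2422 and 324. With genes at 0 in 1 group set to 3 reads per library, the medians of the muscle, mesothelium and choroid plexus lists stayed at -2.67, -3.68 and 0.05. Adjusted over the list alone the counts were 0 higher and 17 lower for fibroblast, 1 higher and 7 lower for pericyte, 0 higher and 7 lower for mesothelium, 0 higher and 5 lower for muscle, 0 higher and 5 lower for erythroid and 1 higher and 2 lower for choroid plexus genes. Single-gene calls were lost for Col1a1, Col3a1 and Rarres2 without brain tumor 2 or 3, for Tagln without brain tumor 3, for Higd1b without brain tumor 1, for Actc1 and Tnni3 without brain tumor 1, 2 or 3, for Hbb-bs without brain tumor 2 or 3 or lung tumor 1, for Hba-a1 without brain tumor 2 or lung tumor 1 and for Aqp1 without brain tumor 1 or 3. Their adjusted p ran from 0.0501 to 0.146 in these fits and over all their alternatives from 0.00103 to 0.146.

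Among lists of cell state, mouse proliferation genes fell in the brain tumors with 9 of 24 members lower (median log2 fold change -1.69, camera adjusted p = 5.38e-06, adjusted p = 0.278 with an estimated correlation). The mitotic kinase gene Aurkb was at 1.46 ± 1.00 RPKM against 22.6 and 10.2 and Tyms at 1.41 ± 0.684 against 38.1 and 12.8. Mcm3 was at 8.78 ± 4.93 against 56.2 and 39.0 and Bub1b at 2.59 ± 1.61 against 13.7 and 15.0. Immediate early genes fell with 8 of 14 lower and 1 higher (median log2 fold change -1.66, camera adjusted p = 0.000474, adjusted p = 0.238 with an estimated correlation). Dusp1 was at 26.6 ± 6.55 against 116 and 261 and Egr2 at 2.91 ± 2.83 against 18.7 and 32.0. Ier2 was at 8.76 ± 2.67 against 99.7 and 57.8. Ier3 was at 18.6 ± 5.98 against 224 and 98.6 RPKM. Hypoxia genes fell with 3 of 16 lower (median log2 fold change -2.10, camera adjusted p = 0.009996, adjusted p = 0.488 with an estimated correlation), the vessel growth factor gene Vegfa at 93.7 ± 17.8 against 430.4 and 1212. P4ha2 was at 23.3 ± 8.79 against 357 and 98.5 and Angptl4 at 12.8 ± 3.38 against 86.6 and 55.1 RPKM. Cytosolic ribosomal protein genes fell as a list (median log2 fold change -1.49, camera adjusted p = 0.000417, adjusted p = 0.404 with an estimated correlation) with 0 of 21 past limma's per-gene test and 8 at an unadjusted p under 0.05, for example Rps3 at 306 ± 48.9 against 3396 and 447. Rpl8 was at 332 ± 27 against 2816 and 477 RPKM. Mitochondrially encoded genes rose with 2 of 7 (median log2 fold change 1.85, camera adjusted p = 0.00685, adjusted p = 0.446 with an estimated correlation), mt-Nd1 at 4351 ± 359 against 1317 and 1680, and mt-Nd5 was at 1875 ± 190.0 against 178 and 747 RPKM. Cholesterol synthesis genes (median log2 fold change 0.35, camera adjusted p = 0.605, adjusted p = 0.875 with an estimated correlation) and nuclear respiratory chain genes (median log2 fold change 0.23, camera adjusted p = 0.319, adjusted p = 0.821 with an estimated correlation) did not pass. In these lists 0 of 18 and 0 of 21 members passed limma's per-gene test, 0 and 4 had an unadjusted p under 0.05, and Cyp51 stood at 63.9 ± 16.7 against 40.0 and 62.0. Atp5b was at 1553 ± 218 against 1196 and 747 and Atp5a1 at 1196 ± 212 against 1038 and 589.6 RPKM. Counts adjusted over the list alone were 0 higher and 17 lower for proliferation, 1 higher and 8 lower for immediate early, 0 higher and 3 lower for hypoxia, 0 higher and 0 lower for ribosomal, 7 higher and 0 lower for mitochondrially encoded, 0 higher and 0 lower for cholesterol and 0 higher and 0 lower for nuclear respiratory chain genes. In all, 30 of 35 mouse lists passed camera with its preset correlation (6 higher, 24 lower), 19 passed fry (5 higher, 14 lower), and 0 passed camera with an estimated correlation (6 at an unadjusted p under 0.05). The hypoxia median turned to 0.11 without lung tumor 1 (adjusted p = 0.937) and was -0.88 (adjusted p = 0.166) with voom on the recovered reads (adjusted p 8.3e-06 to 0.937 over preset-correlation alternatives). Ribosomal protein genes had -0.56 without lung tumor 1 (adjusted p = 0.00804) and -2.44 without lung tumor 2 (adjusted p = 1.14e-06, and 1.14e-06 to 0.00804 over preset-correlation alternatives). Mitochondrially encoded genes had 1.05 without lung tumor 1 (adjusted p = 0.00225, and 0.00170 to 0.0205 over preset-correlation alternatives). Cholesterol synthesis genes had -0.21 without lung tumor 1. Nuclear respiratory chain genes had 0.90 without lung tumor 1 (adjusted p = 2.88e-05) but -0.41 without lung tumor 2 (adjusted p = 0.0614). They passed at 0.47 (adjusted p = 0.0229) with quantile normalization and 0.54 (adjusted p = 0.0118) with voom on the recovered reads (adjusted p 2.88e-05 to 0.803 over preset-correlation alternatives). Single-gene calls ended for Aurkb without brain tumor 1, 2 or 3 or lung tumor 1, for Tyms, Vegfa, P4ha2, mt-Nd1 and mt-Nd5 without brain tumor 1, 2 or 3, for Mcm3 without brain tumor 2 or 3 or lung tumor 1, for Bub1b and Egr2 without brain tumor 1, 2 or 3 or lung tumor 1 or 2, for Dusp1 without brain tumor 1 or 2 and for Ier3 and Angptl4 without brain tumor 2 or 3. There their adjusted p ran from 0.0503 to 0.216, and over all their alternatives from 0.00129 to 0.469.

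**Figure D4:**
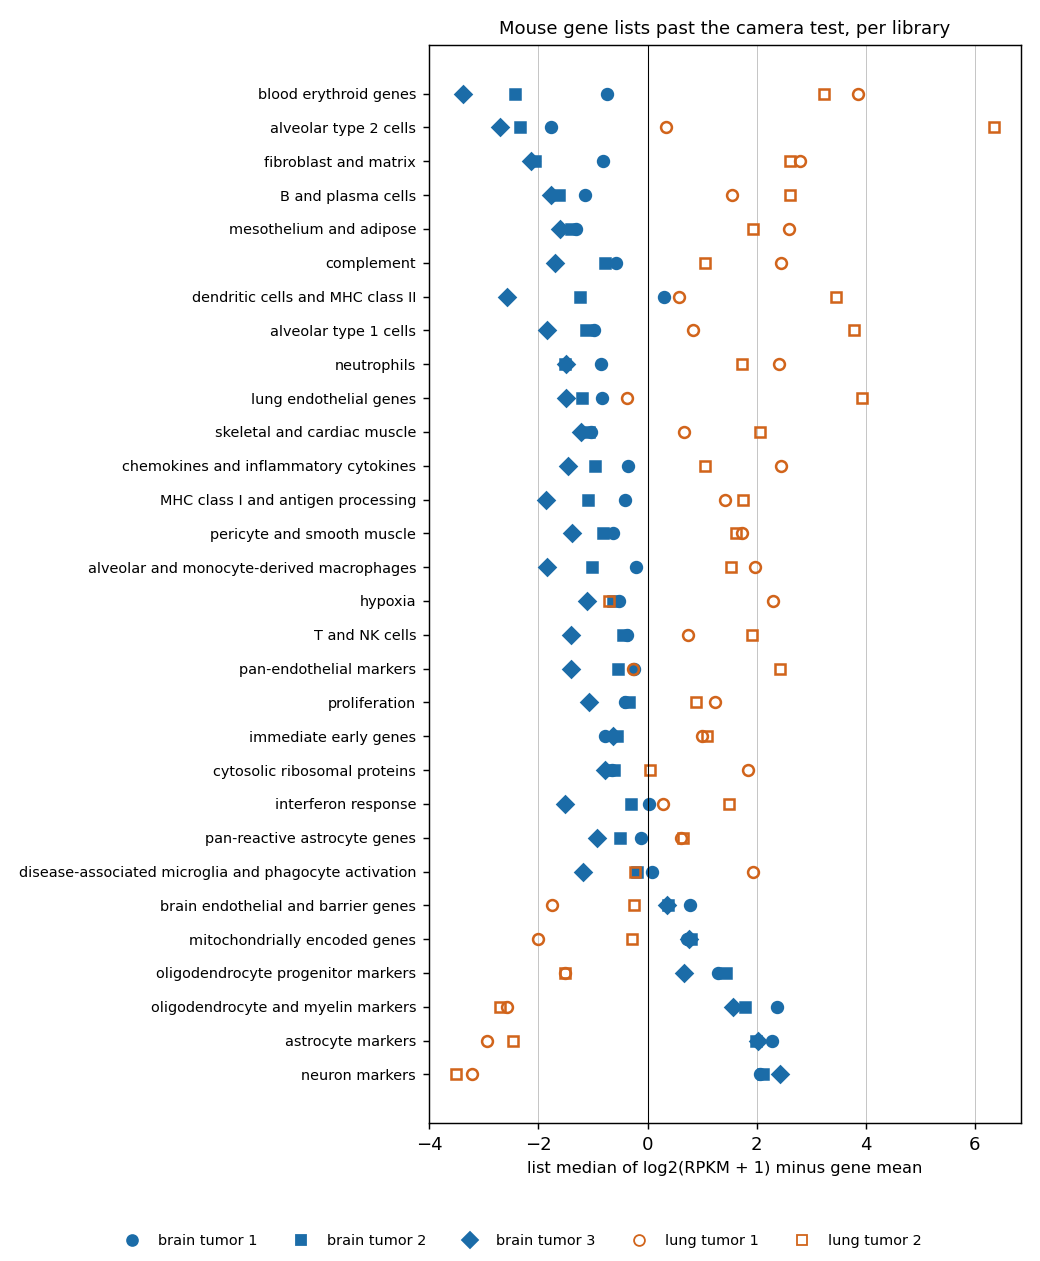
Median over each list's members of log2(RPKM + 1) minus the gene's mean over the 5 libraries (horizontal axis), for mouse lists past the camera test, with 1 point per brain or lung tumor. Neuron markers lay at 2.06, 2.12 and 2.42 in brain tumors 1, 2 and 3 and at -3.22 and -3.52 in lung tumors 1 and 2.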

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

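Voom, gene-length correction and the share covariate were chosen only after the results were seen, the others by plan. The count of human genes past the threshold, 1 in all 5 libraries, was 114 with the replicate block (53.5% higher), 0 with voom, 0 with the share covariate and 0 to 1905 when 1 library was left out. The cause was not tested. The other 11 human alternatives called IGFBP5 alone. The count of mouse genes, 3457 in all 5 libraries, was 2295 with no filter, 1484 with the replicate block, 1467 with treat, whose test asks for a larger change, and 1195 to 8275 when 1 library was left out; the cause was not tested for the others. With the other alternatives it was 2869 to 4233. Of 3457 mouse genes 1 changed sign in 1 alternative, voom. Of 115 called mouse genes named by the rule 0 changed sign in alternatives other than leaving out a library, and calls were lost for 26 with no filter, 25 with the replicate block and 39 with treat, against 0 to 10 in the others; without brain tumor 1, 2 or 3 the loss was 41, 56 and 50, and without lung tumor 1 or 2 it was 14 and 4. The replicate block rests on 2 pairs not given by the labels and takes nothing from brain tumor 3, so it changes 2 things at once. The human proliferation, mouse pan-reactive astrocyte and homeostatic microglia lists changed sides of the threshold with the block and also without brain tumor 3. Across genes the difference of brain tumors 1 and 2 had a correlation of -0.0198 (human) and 0.0533 (mouse) with that of lung tumors 1 and 2. Of 11 human and 30 mouse lists past camera, 0 and 0 passed with an estimated correlation and 0 and 19 in fry. Human hypoxia, glycolysis and NF-kB lists passed in 18 of 18 alternatives that kept camera's preset correlation. Human nuclear oxidative phosphorylation genes ranged from -1.13 to 0.13 when 1 library was left out, interferon genes from -1.25 to 1.33, ribosomal protein genes from -1.25 to 0.37, the mouse hypoxia list from -3.05 to 0.11, the mouse airway list from -2.63 to 1.21 and mouse nuclear oxidative phosphorylation genes from -0.41 to 0.90, each changing sign when 1 lung tumor was left out; the cause was not tested. The human astrocyte list turned to -1.05 (adjusted p = 0.0328, range 0.0328 to 0.883 over preset-correlation alternatives) with wrong-species candidates left out. That left 3 of 7 members and favours dropping those higher in the brain, so the turn decides nothing. Sign changes of lists that were not past the threshold in either fit are counted as no change. Mouse depth of 231156 reads in lung tumor 1 limits genes of low level. Under the filter at an RPKM of 5, human neural progenitor and endothelial lists and mouse T and NK cells had too few members for a test, as had the endothelial list with wrong-species candidates left out.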

Other observations

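Haptoglobin went opposite ways in the cancer cells and the host. Human HP had 137, 48.3 and 46.4 RPKM in the brain tumors and 7.02 and 3.60 in the lung tumors, while mouse Hp had 1.34, 1.04 and 0.675 and 157 and 603. HP was not called (limma adjusted p = 0.304), Hp was (0.00177), and the difference between the species was not tested. A pair of human genes reported as brain metastasis mediators had values of opposite direction. SERPINI1, which encodes neuroserpin, an inhibitor of plasminogen activators, had 39.4 ± 9.93 RPKM in the brain and 8.12 ± 2.30 in the lung tumors, and HBEGF, an EGF receptor ligand, had 6.15 ± 2.17 and 49.9 ± 49.5; both were picked after their values were seen and neither passed (limma adjusted p = 0.304 and 0.429).

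Host lists varied between brain tumors, immune ones and others. List medians of log2(RPKM + 1) minus the gene mean were 1.21, 0.99 and -0.91 in brain tumors 1, 2 and 3 for homeostatic microglia. They were 0.30, -1.25 and -2.58 for dendritic cells and MHC class II, -0.81, -2.06 and -2.14 for fibroblasts and -0.75, -2.43 and -3.38 for erythroid genes. Neuron markers went the other way (2.06, 2.12 and 2.42). Brain tumor 3, lowest in the 4 lists before, held 22.1% human reads, against 75.6% and 56.5% in brain tumors 1 and 2. With 3 libraries no relation to that share was tested.

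All tests below were chosen only after the result was seen. Human genes at least 2-fold higher in brain tumor 2 than in both lung tumors might be mouse reads assigned to human genes. Brain tumors 1 and 3 took no part in choosing them. Brain tumor 3 had more mouse reads per human read than brain tumor 1, so such genes would have risen between these libraries by a median predicted ratio of 10.2 (quartiles 6.83 and 13.03). The observed median ratio over 455 genes with a same-symbol mouse gene was 1.22 (quartiles 0.758 and 1.93), which argues against mouse reads as the source of most of this pattern. Single genes stay open, and a biological effect of growth in the brain was not tested apart from other differences between the groups.

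Lung tumors 1 and 2 differed in both tables, and same-symbol genes of both species tended to differ alike. Across 2014 genes, which are not independent replicates, Spearman's rho was 0.581, against at most 0.226 in brain pairs; sampling noise in the low mouse depth of lung tumor 1 would give no such relation. Among 561 genes with at least 10 mouse reads per 100 human reads in lung tumor 1, rho was 0.478 (brain pairs at most 0.2002 over 1116 to 1463 genes). Choosing genes by their reads in lung tumor 1 itself favours such a relation, so human reads in the mouse table stay open as a source. After correction for gene length rho over the same 2014 genes was 0.472 (brain pairs at most 0.213 over their own 7769 to 8474 genes). This argues against length as the whole source in these genes, though their choice by reads may add to the rest. A difference in RNA or preparation that touches both species may remain, and so may a true difference between the tumors. Neither was tested.

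The human hypoxia and NF-kB lists were lower in the brain tumors. A single library is not the whole source, since the medians nearest to 0 with 1 library left out were -0.87 for hypoxia and -0.54 for NF-kB. Gene-length correction gave -0.99 and -1.32, and the share of human reads as a covariate -0.87 and -1.21, which argues against a length trend and against the share of host tissue as the whole source. The same covariate ended the calls of the human nuclear respiratory chain and ribosomal protein lists, at -0.37 (adjusted p = 0.137) and -0.18 (adjusted p = 0.144). Their adjusted p ran from 2.55e-07 to 0.145 and from 4.33e-14 to 0.269 over preset-correlation alternatives, and for these the share of host tissue stays open. The mouse hypoxia list was lower in the brain tumors too, but turned to 0.11 without lung tumor 1 (adjusted p = 0.937, and 8.3e-06 to 0.937 over preset-correlation alternatives). The growth site is the study's own grouping and was not tested apart from tumor size, time or dissection. The hypoxia and NF-kB calls rest on camera's preset correlation, with adjusted p = 0.764 for each with an estimated correlation.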
